A study of Teleaulax amphioxeia
Mesodinium rubrum and Teleaulax amphioxeia with 4 samples.

How the data were processed

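RNA of the cryptophyte alga Teleaulax amphioxeia growing on its own, and RNA of the ciliate Mesodinium rubrum fed with this alga and then kept without prey for 1, 8 or 13 weeks, was hybridised to a custom Agilent array of cryptophyte transcripts. Per the labels, total RNA was extracted with Trizol, amplified and labelled with Cy3, so each sample is 1 array with 1 colour. The 4 arrays lay on 1 slide and were scanned in 1 session at 5 micrometres, so slide and scan did not differ between samples. Each group held 1 array. The difference between any 2 samples therefore has no replicate check, no statistical test was run and no p-value is given.

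The deposited values are intensities, as brightness of a spot on a linear scale. Per the file headers, they were made with Agilent Feature Extraction 10.7.3.1 and its protocol GE1_107_Sep09, each array on its own. Per the file headers, the processed intensity had its background subtracted and its spatial trend removed, carried a surrogate value where a spot was not above background, and was not normalized between arrays. The same files hold flags for spots well above background, saturated spots and outlier spots. The authors' value table, deposited beside the scanner output, held linear intensities with no scaling between arrays and no centring. It equalled the mean of the 2 spots of a probe, to within 0.0001 of its value, for 93.8%, 94.2%, 94.1% and 93.6% of the probes of the free-living, 1-week, 8-week and 13-week arrays, and nearly all other values equalled the only spot well above background. Its column medians were 16.2, 11.9, 9.82 and 13.3 units in the same order.

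The array carried 15654 probes of 60 bases, 1 for each of 15654 transcripts, each spotted at 2 places. The files pair each probe with a transcript identifier and with no product name, and no genome was used here. The 39 lists of gene functions drawn up before the data were examined were to be matched on product names, so 0 lists had the minimum of 3 members and no list result is given. The probes held 15642 distinct sequences.

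For each array the processed intensities of the 2 spots of a probe were averaged, leaving out a spot carrying an outlier flag, and log2 of the mean was taken relative to the array's 75th percentile. This value is called the scaled signal. A transcript was counted as detected where both spots were well above background. A comparison took in all transcripts detected on at least 1 of its arrays and not saturated on both. Where a transcript was not detected on one array, its level there was set to the higher of its own signal and the lowest signal of any detected transcript on that array. Such a difference is a lower bound and is given as at least N-fold. Differences of at least 2-fold were counted by size in each of the 6 comparisons. Because the percentile is taken over all probes, a scaled difference is relative to the other probes of the same array, and not an amount per cell. RNA of the Mesodinium samples held ciliate and cryptophyte RNA together.

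The features named in the text were chosen by a rule written before the data were examined. With no product names, the rule takes the 2 highest and 2 lowest features of a comparison, measured on both arrays with no saturated spot and no outlier flag. The text names those of 1 week against free-living and of 13 weeks against 1 week, and follows them through all arrays. The error printed with them is the standard deviation of the 2 spots, which covers spot noise and not the spread between cultures, extractions or labelling reactions.

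The counting step was tested on simulated data before use. For 1 week against free-living, with the spot noise of the arrays, all 50 transcripts of each class made 4-fold or 8-fold higher or lower were recovered. They were drawn only from transcripts detected on the free-living array at over 50 units and below a fixed ceiling. Recovery of dimmer transcripts, and of smaller changes, was not tested. On these simulated arrays of 15654 transcripts, 76 of 8826 unchanged ones compared (0.861%) passed 2-fold. To give the level that spot noise alone reaches, 20 sets of 4 arrays without any difference in scaled signal were drawn. The same sets served all 6 comparisons. Intervals of slopes and matched medians are 95% bootstrap intervals over transcripts from 200 draws, and transcripts are not replicates.

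Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, scaling to the median, scaling to the 75th percentile of probes detected on all arrays, no scaling, the authors' value table, no filter on dim probes, a filter to probes detected on all 4 arrays, and a 3-fold threshold. Alternatives added after seeing the data were lowess normalization by signal, setting the median difference of probes detected on both arrays to 0, asking for at least 2-fold in each spot, and detection by 1 spot. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 for normexp. Precision was limited by the number of arrays. The median intensity was 15.8 units on the free-living array and 11.2, 8.82 and 12.4 units on the 1-week, 8-week and 13-week arrays. The standard deviation of a single spot, taken from the 2 spots of each detected probe, was 0.21 to 0.23 on the log2 scale.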

Results

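Mesodinium rubrum is a marine ciliate that eats cryptophyte algae and keeps their plastids, and for a time their nuclei, working inside its own cell. The 4 arrays asked which transcripts of the cryptophyte Teleaulax amphioxeia are present at which level when the alga lives freely, and when its organelles are held in ciliates left without prey for 1, 8 or 13 weeks. Each condition was measured on 1 array, so the differences below describe these 4 RNA samples, with no replicates and no test. The Mesodinium samples also held ciliate RNA, and no array of ciliate RNA alone was used. Ciliate RNA hybridising to the probes could therefore add to any Mesodinium signal below. The 75th percentile of intensity was 103 units on the free-living array and 59.0, 47.7 and 51.3 units on the 1-week, 8-week and 13-week arrays. The 2 spots of a probe correlated at r = 0.99 across transcripts on each array.

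Most of the transcripts detected in the free-living alga were also detected on at least 1 Mesodinium array. On the free-living array 8821 of 15654 transcripts (56.4%) were detected. The numbers were 8319 (53.1%) at 1 week, 7691 (49.1%) at 8 weeks and 8117 (51.9%) at 13 weeks of starvation. Of the transcripts detected in free-living cells, 7402 (83.9%) were detected on at least 1 Mesodinium array, and 6447 were detected on all 4 arrays. A further 1419 transcripts were detected in free-living cells only, and 674 on all 3 Mesodinium arrays but not in free-living cells. Single Mesodinium arrays alone held 151 transcripts at 1 week, 38 at 8 weeks and 401 at 13 weeks. The brightest transcripts were largely shared, as 62 of the 100 brightest were the same on all 4 arrays and 91 were the same on all 3 Mesodinium arrays. Saturated spots occurred in 84, 88, 83 and 56 probes of the free-living, 1-week, 8-week and 13-week arrays, so most of these brightest transcripts lay at the scanner's ceiling and the overlap says nothing of their levels.

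**Figure D1:**
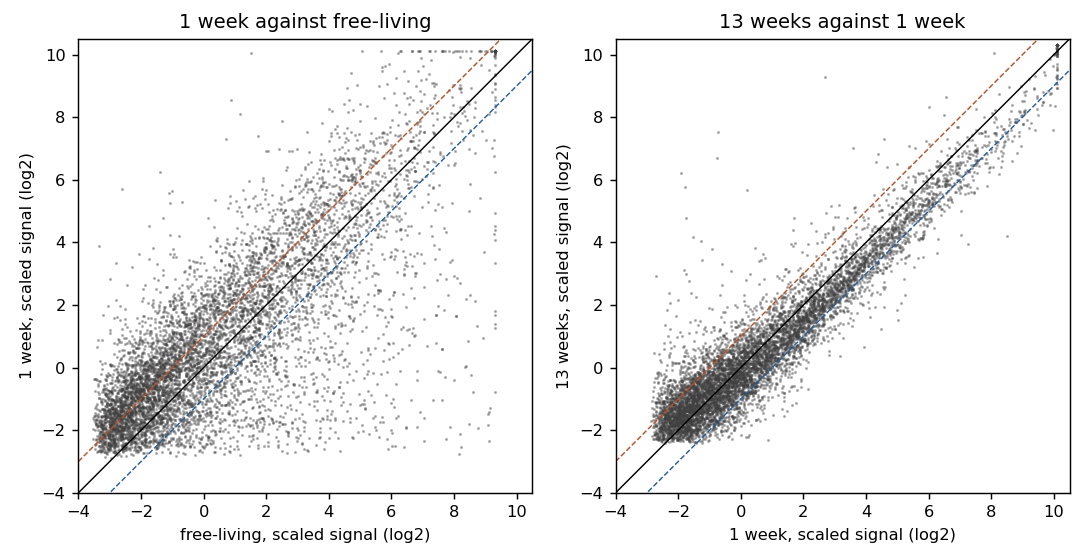
Scaled signal (log2, relative to the 75th percentile of each array) of each transcript detected on both arrays, 1 week against free-living on the left and 13 weeks against 1 week on the right. The solid line marks equal signal and the dashed lines 2-fold differences. The left cloud is wide (r = 0.75) and the right one narrow (r = 0.94), and the flat edges at the top come from saturated spots.

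The first comparison asked how signals on the cryptophyte probes at 1 week differed from those of free-living cells. The lowest transcript relative to free-living cells was CUST_1217_PI427587472 (EPT001TT0348C001226, probe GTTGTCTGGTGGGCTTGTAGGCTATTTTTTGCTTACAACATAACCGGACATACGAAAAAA), with an intensity of 56869 ± 1020 (SD of 2 spots) in free-living cells and 11.7 ± 0.807 at 1 week, a log2 difference of -11.45. Second was CUST_526_PI427587472 (EPT001TT0348C000530, probe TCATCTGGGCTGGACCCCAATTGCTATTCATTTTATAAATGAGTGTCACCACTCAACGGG), with 56490 ± 3374 in free-living cells and 16.4 ± 0.627 at 1 week, a log2 difference of -10.95. Neither was detected at 8 or 13 weeks. The highest was CUST_1384_PI427587472 (EPT001TT0348C001394, probe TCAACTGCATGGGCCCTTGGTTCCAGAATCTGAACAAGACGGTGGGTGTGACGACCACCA), at 17.0 ± 2.34 in free-living cells and 3066 ± 64.9 at 1 week, which was 315-fold higher on the scaled arrays. It was followed by CUST_2640_PI427587472 (EPT001TT0348C002659, probe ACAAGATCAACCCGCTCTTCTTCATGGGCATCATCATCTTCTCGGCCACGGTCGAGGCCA), at 190 ± 42.6 and 22139 ± 4170, a 203-fold difference. Under the alternative settings the log2 differences of these 4 transcripts lay between -12.25 and -9.21, -11.75 and -9.07, 5.88 and 8.30, and 6.86 and 7.67, in the order given.

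Of 9903 transcripts compared at 1 week, 5944 differed from free-living cells by at least 2-fold, 3833 of them higher and 2111 lower. Differences of at least 16-fold were more often lower (562) than higher (117). Among transcripts detected in free-living cells with neither spot well above background at 1 week, 716 of 1333 were at least 2-fold lower, the largest difference being at least 1768-fold. Signals on the 2 arrays correlated at r = 0.75 across transcripts, which are not independent replicates. Arrays without any difference, simulated with the spot noise, gave 97.0 transcripts past 2-fold on average and 119 at most. The split between higher and lower depended on the scaling and background correction. The transcripts measured on both arrays had a median difference of 0.68 on the log2 scale. The share of higher among differing transcripts was 64.5%, against 49.7% with normexp, 53.7% with median scaling, 38.2% with the median difference set to 0, 38.2% with lowess and 33.0% without scaling. The count of 5944 became 2775 with normexp, 3824 among only the probes detected on all arrays and 3715 at 3-fold. Under every one of the 9 scalings and background corrections tried, 2 of them chosen after seeing the data, 1113 transcripts were at least 2-fold higher and 1268 at least 2-fold lower.

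**Figure D2:**
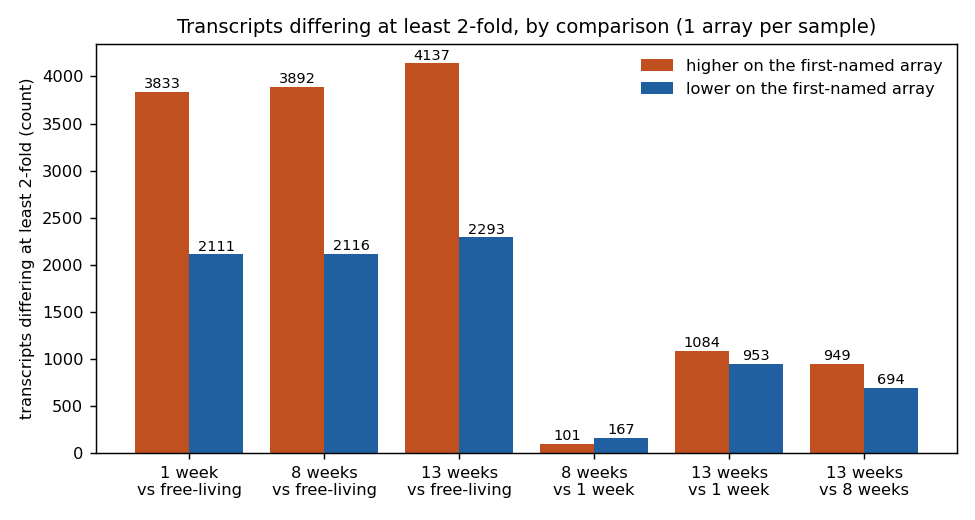
Number of transcripts differing at least 2-fold in each of the 6 comparisons, with 1 array per sample; bars show those higher (orange) and lower (blue) on the array named first. Comparisons with free-living cells hold 5944 to 6430 transcripts, 8 weeks against 1 week holds 268, and the orange and blue shares against free-living cells exchange places when arrays are not scaled.

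Most of the transcripts that differed from free-living cells at 1 week differed in the same direction at 8 and 13 weeks. CUST_1384_PI427587472 had a log2 difference from free-living cells of 8.65 at 8 weeks and 7.43 at 13 weeks, and CUST_2640_PI427587472 had 8.69 and 8.07. For CUST_1217_PI427587472 the bounds were -11.71 at 8 weeks and -11.55 at 13 weeks, and for CUST_526_PI427587472 they were -11.70 and -11.46. At least 2-fold lower at all 3 times were 1782 transcripts, which is 84.4% of those lower at 1 week. At least 2-fold higher at all 3 times were 2792, which is 72.8% of those higher at 1 week. The higher set depended on the setting, with 675 transcripts under normexp, 747 without scaling, 1111 with the median difference set to 0, 1208 with lowess, 1623 with median scaling, 1367 at 3-fold and 4230 with no filter on dim probes, and the lower set was 2979 without scaling, 2752 with lowess and 832 among only the probes detected on all arrays. The sets with differences of at least 16-fold at all 3 times held 464 lower and 71 higher transcripts. With normexp these were 233 and 13, with only probes detected on all arrays 145 were lower, and the higher set was 33 without scaling, 45 with median scaling, 38 with the median difference set to 0, 42 with lowess and 107 with no filter on dim probes. Under every one of 9 scalings, 1112 transcripts were lower and 512 higher at all 3 times.

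Against free-living cells, 6008 of 9666 transcripts differed at 8 weeks (3892 higher, 2116 lower) and 6430 of 10050 at 13 weeks (4137 higher, 2293 lower). Simulated arrays without any difference gave 139 and 180 on average. With normexp 2772 and 2926 differed, and among only the probes detected on all arrays 3997 and 4018. At 3-fold 3814 differed at 8 weeks, and with no filter on dim probes 10935 did at 13 weeks. The median differences of transcripts measured on both arrays were 0.82 and 0.69. The share of higher was 64.8% at 8 weeks, against 48.2% with normexp, 33.9% with the median difference set to 0, 34.6% with lowess and 23.4% without scaling. At 13 weeks it was 64.3%, against 42.2% with normexp, 43.3% with median scaling, 42.2% with the median difference set to 0, 38.8% with lowess and 30.3% without scaling. The scaled detection limit was -3.53 in free-living cells and -2.44 at 13 weeks, and all 840 transcripts detected at 13 weeks with neither spot well above background in free-living cells were at least 2-fold higher, since the gap between the limits alone exceeds 2-fold.

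The 3 comparisons with free-living cells share 1 array, and chance values of that array enter all of them. Differences at 1 and 8 weeks correlated at r = 0.98 across 6684 transcripts, where simulated arrays without any difference gave 0.43. The covariance was 3.70 against 0.028 in the simulation. For 1 and 13 weeks r was 0.90 against 0.41, with a covariance of 3.35 against 0.027. For 8 and 13 weeks r was 0.91 against 0.43, with a covariance of 3.44 against 0.027. Transcripts higher at both 1 and 13 weeks numbered 2970, where independent lists would share 1403, and those lower at both numbered 1824, against 504. For 1 and 8 weeks the shared numbers were 3439 higher against 1461 and 1951 lower against 466. For 8 and 13 weeks they were 2978 higher against 1404 and 1901 lower against 512. The simulation holds the spot noise of the shared array, which gave only its small covariances. It does not hold variation between cultures, extractions or labelling reactions. With 1 free-living RNA sample that variation cannot be separated, so part of the excess may come from the shared control.

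Between 1 and 8 weeks of starvation the transcript levels lay close together. CUST_1384_PI427587472 had an intensity of 3066 ± 64.9 at 1 week and 3146 ± 24.1 at 8 weeks, a log2 difference of 0.34, and CUST_2640_PI427587472 had 22139 ± 4170 and 36526 ± 6370, a log2 difference of 1.03. Of 8362 transcripts, 268 (3.20%) differed at least 2-fold, 101 higher and 167 lower at 8 weeks. Simulated arrays without any difference gave 85.8 on average and 100 at most. The count was 64 with normexp (18 higher, 46 lower), 58 at 3-fold, 426 without scaling, 509 with detection by 1 spot and 1076 with no filter on dim probes. The arrays correlated at r = 0.99 across transcripts, and their median difference was 0.022. No transcript was at least 16-fold lower and 1 was at least 16-fold higher. The share of higher was 37.7%, against 11.03% without scaling, and it turned to 53.2% (271 higher, 238 lower) with detection by 1 spot, a setting chosen after seeing the data. In all 15 transcripts were higher and 40 lower under every one of 9 scalings.

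The last array of the series, at 13 weeks, stood further from 1 week than 8 weeks did. The highest transcript relative to 1 week was CUST_4545_PI427587472 (EPT001TT0348C004581, probe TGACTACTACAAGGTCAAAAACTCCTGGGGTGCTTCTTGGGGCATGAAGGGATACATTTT). Its intensity was 522 ± 54.2 in free-living cells, 35.8 ± 0.103 at 1 week, 52.0 ± 1.78 at 8 weeks and 9498 ± 56.1 at 13 weeks, which was 305-fold above 1 week on the scaled arrays. CUST_3916_PI427587472 (EPT001TT0348C003945, probe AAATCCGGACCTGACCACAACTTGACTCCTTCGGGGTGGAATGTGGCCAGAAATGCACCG) was next, with 15.8 ± 4.62 at 1 week, 46.0 ± 5.82 at 8 weeks and 3859 ± 73.7 at 13 weeks, a 280-fold difference, and it was not detected in free-living cells. The lowest was CUST_342_PI427587472 (EPT001TT0348C000345, probe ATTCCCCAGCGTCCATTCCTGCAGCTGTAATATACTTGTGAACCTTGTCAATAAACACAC), with 12654 ± 1643 in free-living cells, 21453 ± 4025 at 1 week, 3576 ± 429 at 8 weeks and 948 ± 114 at 13 weeks, a log2 difference of -4.30 from 1 week. CUST_15103_PI427587472 (EPT001TT0348C015913, probe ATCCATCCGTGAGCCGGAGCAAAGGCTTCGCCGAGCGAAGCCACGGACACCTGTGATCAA) came second, with 17186 ± 719, 1914 ± 125, 445 ± 53.7 and 149 ± 5.65 in the same order, a log2 difference of -3.49. Under the alternative settings the log2 differences of these 4 transcripts lay between 6.59 and 8.79, 5.68 and 8.58, -4.66 and -3.56, and -3.84 and -2.96.

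**Figure D3:**
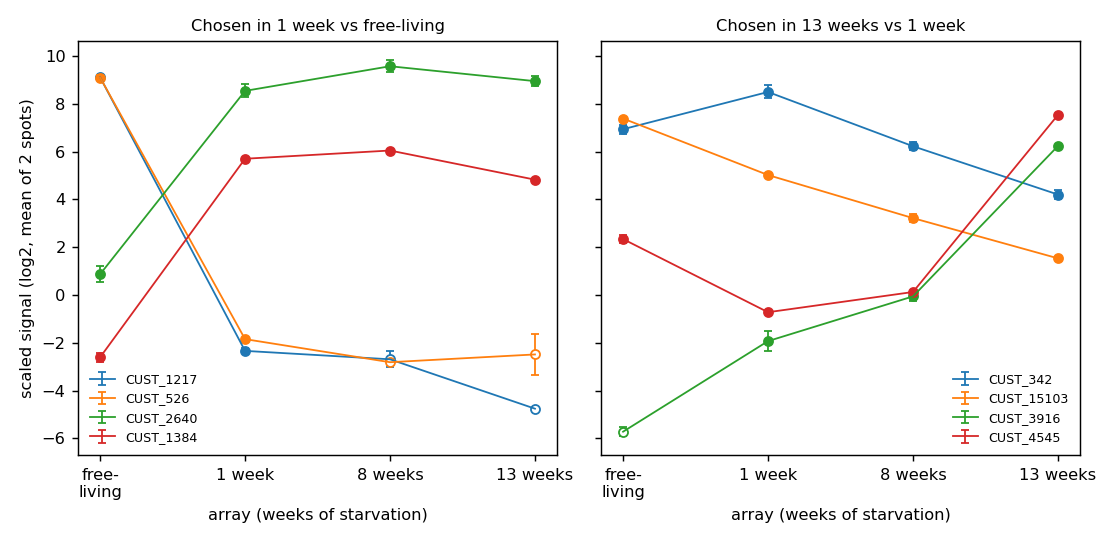
Scaled signal (log2) of the 8 named transcripts on the 4 arrays, those chosen at 1 week against free-living on the left and at 13 weeks against 1 week on the right. Points are means and bars the standard deviation of 2 spots, and open points were not detected. CUST_4545 and CUST_3916 have their highest values at 13 weeks, and CUST_342 and CUST_15103 have lower values at 8 than at 1 week and lower values again at 13 weeks.

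At 13 weeks 2037 of 8896 transcripts differed from 1 week by at least 2-fold, 1084 higher and 953 lower, and 1643 of 8569 differed from 8 weeks, 949 higher and 694 lower. Simulated arrays without any difference gave 91.1 and 98.8 on average. They held spot noise only, and not the narrower spread of signals at 13 weeks described below. Against 1 week, 305 transcripts were higher and 103 lower in the dimmest of the equal groups used there. In the brightest group 66 were higher and 424 lower. Against 8 weeks these were 288 and 81, and 62 and 327. Part of the excess may therefore reflect the narrower spread. With lowess normalization by signal 1671 and 1328 differed. The 2037 and 1643 became 782 and 515 with normexp, 599 and 424 at 3-fold, and 3763 and 3515 with no filter on dim probes. Against 1 week 1347 differed among only the probes detected on all arrays, and against 8 weeks 2916 differed with median scaling. Higher than both earlier times at 13 weeks were 783 transcripts, and 430 were lower than both. At least 16-fold above both earlier times were 21 transcripts, among them CUST_4545_PI427587472 and CUST_3916_PI427587472, and 0 were 16-fold below both. The 21 became 7 with normexp, 13 among only the probes detected on all arrays and 42 with no filter on dim probes. All 21 were also at least 2-fold above free-living cells, and 15 of them were detected there. The arrays correlated at r = 0.94 with 1 week and r = 0.95 with 8 weeks across transcripts. Higher and lower numbers depended on scaling at this time. The share of higher against 1 week was 53.2%, and it was 17.3% with normexp, 21.9% with median scaling, 33.2% without scaling, 66.6% with the median difference set to 0, 86.5% with scaling to probes detected on all arrays, and 38.5% among only the probes detected on all arrays. Against 8 weeks it was 57.8%, and it was 26.4%, 16.4%, 71.6%, 85.6%, 92.8% and 44.3% under the same settings and 70.8% with lowess. Under every one of 9 scalings, 134 transcripts were higher and 161 lower than at 1 week, and 131 higher and 38 lower than at 8 weeks.

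Differences from free-living cells varied with the base composition of the probes. At 1 week the median log2 difference was -0.32 for probes with up to 40% G+C, 0.52 for those over 40 to 50%, 0.84 for those over 50 to 60% and 1.01 for those over 60%. At 13 weeks the 4 medians were -0.83, 0.36, 0.95 and 1.21, and at 8 weeks they were -0.43, 0.64, 0.97 and 1.06. Between 13 weeks and 1 week they were -0.52, -0.34, 0.0080 and 0.041. Scaling an array by another single factor shifts its 4 medians together and leaves the gaps between them, so their signs depend on the scaling factor. Transcripts lower at all 3 times than in free-living cells had a median probe G+C content of 45.0%, and those higher at all 3 times had 55.0%. The median was also 55.0% for transcripts detected on all 4 arrays, and it was 53.3% for all probes.

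**Figure D4:**
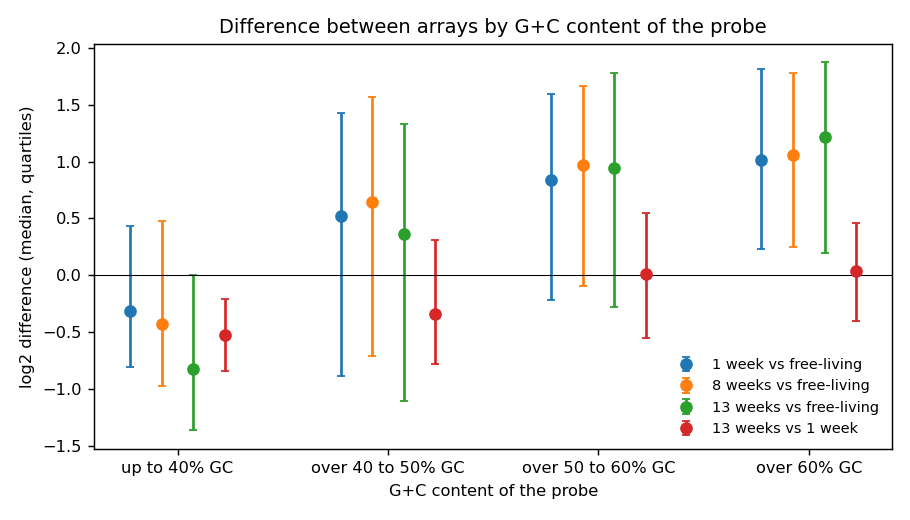
Median log2 difference between arrays (bars from the lower to the upper quartile over transcripts) in 4 classes of probe G+C content, for 4 comparisons. The medians against free-living cells go from -0.32, -0.43 and -0.83 in the class up to 40% to 1.01, 1.06 and 1.21 in the class over 60%, and their sign depends on the scaling.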

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

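Control probes, which no comparison used, gave a signal above the negative controls on some arrays. The bright corner spots, which mark the array's orientation, had the highest median intensity of any control, 989 units at 1 week, and 410, 734 and 790 units on the free-living, 8-week and 13-week arrays. The spike-in probe E1A_r60_a22 was brightest on the free-living array, at 137 units, and had 56.6, 60.7 and 22.6 units at 1, 8 and 13 weeks. A group of DCP_22 control probes ran the same way, with highest medians in free-living cells of 156 units for DCP_22_0, 134 for DCP_22_2, 39.7 for DCP_22_4, 53.7 for DCP_22_6, 45.6 for DCP_22_7 and 12.4 for DCP_22_9. DCP_22_0 had 59.4, 65.3 and 23.4 units at 1, 8 and 13 weeks. For DCP_20 controls the highest medians were 12.9 units for DCP_20_0, 12.5 for DCP_20_7 and 19.3 for DCP_20_9, all at 8 weeks, and 11.8 for DCP_20_3 at 1 week. E1A_r60_1 reached 12.6 units and ETG05_66023 17.6 units, both at 13 weeks, and eQC-39 reached 9.30 units at 1 week. Of the 10 E1A probes only 1 was well above background on all 4 arrays.

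A few transcripts changed side against free-living cells between early and late starvation. At 1 week 6 were at least 2-fold higher and at 13 weeks at least 2-fold lower, and 13 were lower at 1 week and higher at 13 weeks. CUST_4545_PI427587472 was one of the latter, with log2 differences of -3.06 at 1 week and 5.19 at 13 weeks. The difference between the times was not tested, as each time had 1 array.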

How the results depend on the processing

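The lowess, centring, both-spot and 1-spot settings were chosen after seeing the data. Of the counts and shares recomputed under alternatives, 96 counts stayed within 1.5 times the main count, and 47 values moved (the 4 detection shares among them). The majority direction turned in each comparison under at least 1 setting, with the shares given beside the counts above. For single named features 141 values stayed within the error of a 2-spot mean difference, from the typical spot SD of each array and not that of the feature, 119 moved and 0 reversed. Settings that only filter probes cannot change the value of a feature measured on both arrays, so many of the 141 were fixed by construction. The features were picked as the largest differences, so a reversal was unlikely from the start. The tally is therefore no measure of robustness. Counts under normexp were 2775, 2772 and 2926 for 1, 8 and 13 weeks against free-living, 64 for 8 weeks against 1 week, 782 and 515 for 13 weeks against 1 and 8 weeks, 675 higher at all 3 times than free-living, 233 at least 16-fold lower and 13 at least 16-fold higher at all 3 times, and 7 at least 16-fold higher at 13 weeks than at 1 and 8 weeks. The 3-fold threshold, stricter by construction, gave 3715 and 3814 for 1 and 8 weeks against free-living, 58 for 8 weeks against 1 week, 599 and 424 for 13 weeks against 1 and 8 weeks, and 1367 higher at all 3 times. Only probes detected on all 4 arrays, fewer by construction, gave 3824, 3997 and 4018 against free-living, 1347 for 13 weeks against 1 week, 832 lower and 145 at least 16-fold lower at all 3 times, and 13 at least 16-fold higher at 13 weeks. With no filter on dim probes, more probes being counted, these were 10935 for 13 weeks against free-living, 1076 for 8 weeks against 1 week, 3763 and 3515 for 13 weeks against 1 and 8 weeks, 4230 higher and 107 at least 16-fold higher at all 3 times, and 42 at least 16-fold higher at 13 weeks. Detection by 1 spot gave 509 for 8 weeks against 1 week, and 62.5%, 58.9%, 55.0% and 58.2% of transcripts detected in free-living, 1-week, 8-week and 13-week samples. Without scaling the values were 426 for 8 weeks against 1 week, and at all 3 times 747 higher, 2979 lower and 33 at least 16-fold higher. Median scaling gave 2916 for 13 weeks against 8 weeks, 1623 higher and 45 at least 16-fold higher at all 3 times. Setting the median difference to 0 gave 1111 higher and 38 at least 16-fold higher at all 3 times, and lowess 1208 higher, 2752 lower and 42 at least 16-fold higher. For normexp and the scalings the cause was not tested. Not run were scaling to the E1A spike-ins, of which 1 of 10 was well above background on all arrays, other summaries of several probes per gene, as each transcript has 1 probe, and the gene lists, as the files hold no product names. No paired analysis was possible because each group has 1 array. In all 5221 transcripts were not detected on any array, and signals near the detection limit bound the differences of dim transcripts.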

Other observations

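The tests with the raw 75th percentile and with the negative control spots were chosen after the results were seen, and the other tests below were written down beforehand. Few transcripts differed in the same direction at both steps of starvation. At least 2-fold lower at 8 weeks than at 1 week and again at 13 weeks than at 8 weeks were 26 transcripts, and 10 were higher at both steps. Both numbers come from the main setting only, with no chance level beside them, and the 2 steps share the 8-week array. No steady trend with starvation can be read from them. All 100 of the brightest transcripts of each Mesodinium array were detected in free-living cells, and 100, 98 and 95 of the 100 brightest free-living transcripts were detected at 1, 8 and 13 weeks.

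The 10 pairs of probes with identical sequence allow a check of precision within an array. In 8 measured pairs the 2 differences from free-living cells were set against each other. The standard deviation of their disagreement, divided by the square root of 2 to give a value per probe, was 0.087 on the log2 scale at 1 week. It was 0.13 at 8 weeks and 0.11 at 13 weeks. The largest gaps within a pair were 0.25, 0.28 and 0.34.

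The 674 transcripts detected on all 3 Mesodinium arrays and not in free-living cells had median intensities of 7.08 units in free-living cells and 18.4, 15.5 and 20.7 units at 1, 8 and 13 weeks. Whether spot noise is their source cannot be decided by the simulation. Its 20 sets of arrays, unchanged in scaled signal, gave 5.05 such transcripts on average and 10 at most. Equal scaled signal put each simulated transcript at a higher intensity on the free-living array, while the unscaled limits given below lie close together. The pattern could therefore hardly arise in these sets. Whether a dimmer free-living array is the source of the 674 transcripts cannot be decided here either. The raw 75th percentile of that array was 1.75 times the highest of the others (interval 1.66 to 1.87). Its scaled detection limit was the lowest. The Mesodinium samples held ciliate RNA too, which by itself can lower their percentile, and the limit is scaled by that percentile. Unscaled, the lowest detected signal was 8.92 units in free-living cells and 8.04, 7.87 and 9.46 units at 1, 8 and 13 weeks. Control spots went both ways. The bright corner spots were dimmest on the free-living array, at 410 units against 989, 734 and 790. The spike-in probe E1A_r60_a22 was brightest there, at 137 units against 56.6, 60.7 and 22.6, and so were the DCP_22 controls named above. A bound of 4-fold over the free-living limit, set beforehand against a dimmer array, was met at 13 weeks only. The median transcript lay 3.60-fold, 3.76-fold and 4.66-fold over that limit at 1, 8 and 13 weeks. RNA of the ciliate hybridising to these probes stays open. Against transcripts of like signal, the set moved by -0.12 (interval -0.20 to -0.052) from 1 to 13 weeks. This estimate is above the -0.2 set beforehand for ciliate RNA, but the interval reaches that limit, and transcripts of the cryptophyte that held their level would give the same value. No array of ciliate RNA alone was used here, so ciliate RNA and transcripts made in the sequestered state cannot be told apart.

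Signals at 13 weeks were less spread out than at 8 weeks, with a slope of 0.904 (interval 0.898 to 0.909) of log2 intensity on log2 intensity, where 8 weeks on 1 week gave 1.01. The median scaled difference was 0.17, -0.32 and -0.66 in the dimmest, middle and brightest of 3 equal groups of transcripts. Saturated spots are argued against, as the slope without them was 0.890. Before background subtraction, negative control spots were 1.07 units brighter at 13 than at 8 weeks. Subtracting this from the processed 13-week intensities left a slope of 0.915 (interval 0.909 to 0.922). Those intensities already had their background subtracted, so this value does not decide whether some background remained. An additive background may still contribute, because above 500 units the slope was 0.951 (interval 0.934 to 0.969), which spans the value set beforehand. A change of RNA composition with starvation was not tested and cannot be told apart from such a background.

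Prey cells left over in the 1-week culture could have raised, at 1 week, the transcripts that were far lower at 8 weeks than in free-living cells. The 511 transcripts at least 8-fold lower at 8 weeks than in free-living cells and detected at 1 or 13 weeks differed between 13 weeks and 1 week by 0.085 (interval -0.032 to 0.184) more than transcripts matched on signal. A value below -0.5 was the mark of leftover prey set beforehand, and a smaller contribution of prey is not excluded. Of the 511 transcripts, 83 were at least 2-fold lower and 83 at least 2-fold higher at 13 weeks. The test bears on the 1-week levels and not on why the transcripts were lower than in free-living cells, for which no explanation was tested.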
